A study of Mus musculus with 12 samples.

How the data were processed

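Polyadenylated RNA of PYMT-R221A cells, a mouse mammary tumour cell line, was extracted with a column kit and sequenced on a NovaSeq X, per the labels' protocols. The 12 libraries fell into 4 groups of 3 by the labels: control, KCC-07 at 40 µM, scramble siRNA and siRNA against Mbd2. The vehicle and the duration of the treatment were not given in the sources used here. The deposited table held whole-number read counts for 55335 genes, with no normalization, and each column was matched to its library by the library name in the labels. The submitters' processing notes name DRAGEN, DESeq2 1.44.0 and the genome build mm10 (GRCm38.p6) without saying which step each served. The annotation, the treatment of multi-mapped reads and the strand setting of the counting were not given in the sources used here. Genes that overlap a gene on the opposite strand, or that have a near-identical copy, are therefore reported as uncertain.

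Total counts ran from 25.8 to 34.0 M per library, and the most abundant gene took at most 1.82% of them. No pair of replicates within a group held identical values, and each such pair differed by more than sampling noise, with a chi-square per degree of freedom of at least 3.38. Genes were kept by edgeR's filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 14935 genes. The counts were scaled by TMM and fitted in R 4.3.3 with edgeR 4.0.16, using glmQLFit and glmQLFTest with 1 mean per group over all 12 libraries, so that the groups shared 1 estimate of the spread (8 residual degrees of freedom). The contrasts were KCC-07 minus control, siMBD2 minus scramble, the difference between those effects, and scramble minus control. A gene passed the threshold at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Standard errors were the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, and levels are TMM-scaled CPM from the cpm function of edgeR. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so single genes were tested only in the model fitted across all genes.

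The design, the alternatives, 36 gene lists from textbook knowledge and the rule for named genes were fixed before the data were examined. Of the list members, 853 were matched to measured genes by symbol, 2 of them under a newer symbol. Lists with at least 5 measured members (34 lists) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and Benjamini-Hochberg adjustment over the 34 lists. Beside it stood camera with an estimated correlation and fry, which tests whether the genes of a set move, on balance, one way and does not compare them with other genes. The genes named by size were, among those past the threshold with a mean of at least 2 CPM and every treated library on 1 side of every control library, the 10 with the largest positive and the 10 with the largest negative log2 fold change per main comparison, leaving out predicted gene models. For the difference of the effects and for scramble against control the rule took 5 and 5, with no condition on library order for the difference. From each list up to 4 members with the smallest adjusted p were eligible, and Mbd2, Mbd3 and Adgrb1 were always named. Some genes that met this rule are not reported here. Members named beyond this rule are said to have been chosen after their values were seen. Gene positions came from the GENCODE annotation of GRCm38.p6, in which 54587 of the 55335 identifiers were found with their version, and a copy was counted as near-identical at 95% identity over 50% of the transcript.

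The labels give each library a batch tag that names it as biological replicate 1, 2 or 3, and this tag paired the libraries of the drug arm and those of the siRNA arm. Deviations from the group means of same-numbered libraries correlated with r = 0.27, 0.28 and 0.48 between control and KCC-07 and with 0.09, 0.15 and 0.42 between scramble and siMBD2 across genes. Differently numbered libraries of replicates 1 and 2 correlated about as much (0.30 and 0.17 in the drug arm, 0.21 and 0.18 in the siRNA arm). The values thus pair the libraries of replicate 3, and the pairing of replicates 1 and 2 rests on the labels. The fit with the replicate number within each arm as a block had 4 residual degrees of freedom. For scramble against control the block was shared by all groups, with 6 residual degrees of freedom. Same-numbered control and scramble libraries correlated with r = 0.07, 0.02 and 0.13, and the library names number replicate 3 as 4 in the drug arm and 3 in the siRNA arm. Whether the arms shared batches is therefore unclear, and the counts with this shared block are uncertain.

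The alternatives were DESeq2 size factors, no filter on low counts, a filter at 1 CPM in 3 libraries, the replicate block, a fit of the 6 libraries of a comparison alone, the Wald test of DESeq2 1.42.0, thresholds of 0.01 and of an absolute log2 fold change of 1, a prior count of 0.5 for the list tests, and leaving out each library in turn. Added after the data were seen were the fits without the libraries of batch 3, with and without the block, the fit of 6 libraries alone with the block, and the block with an estimated correlation. For 3' UTR sequences, every 7-base word was tested over 12534 genes with an annotated 3' UTR of at least 50 bases, as the t statistic of its presence in a linear model of the log2 fold change, limited to an absolute value of 1, with 3' UTR length and GC content as covariates.

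The fits were tested on simulated data with 200 of the 14935 genes changed. In the simulated KCC-07 comparison 9.76%, 60.0% and 86.2% of genes changed by 1.5, 2 and 4 times were recovered, and 4.08% of the calls were false. In the simulated siMbd2 comparison the shares were 18.8%, 68.3% and 91.8%, with 5.43% false. With the block the false share in this simulation was 10.1% in the drug arm (9 false calls against 4 without it) and 6.72% in the siRNA arm (8 against 7). The simulated counts held no replicate effect, and each gene had the same spread in all groups. They therefore do not test the pooled spread or the block where replicates or arms differ, as in the real libraries. In these simulated counts the list test called the planted list and 0 others. In the real drug arm, splits that mixed the labels still gave 5 to 12 lists, and camera with an estimated correlation called 0 lists in the real split. The simulation therefore does not show how often the list test calls unchanged lists in the real libraries. The word test recovered 5 of 5 planted words.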

Results

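Gene expression was measured by RNA sequencing in PYMT-R221A cells, a mouse mammary tumour line, in 4 groups of 3 libraries: control, 40 µM KCC-07, scramble siRNA and siRNA against Mbd2. KCC-07 is a small molecule that the series title places as an inhibitor acting on the MBD2 pathway. MBD2 binds methylated DNA and recruits the NuRD chromatin-remodelling complex. The comparisons ask which genes change with the compound, which change with the knockdown, and whether they are the same genes. The labels name the replicates as biological. They name no vehicle, so an effect of a vehicle in KCC-07 against control is unknown. Deposited counts summed to 29.8 to 34.0 M per control library, 25.8 to 29.2 M with KCC-07, 26.1 to 32.9 M with scramble siRNA and 29.7 to 31.7 M with siMbd2. After filtering, 14935 genes were tested. The libraries of replicate 3 stood apart in each group. Mitochondrially encoded transcripts took 2.81% of the counts in control replicate 3 against 1.45% and 1.47% in the other 2 control libraries, and 3.90% in KCC-07 replicate 3 against 1.82% and 1.55%. They took 3.01% in scramble replicate 3 against 2.21% and 2.32%, and 2.70% in siMBD2 replicate 3 against 2.14% and 2.12%. KCC-07 replicates 1 and 2 differed by a chi-square per degree of freedom of 9.69, and each differed from replicate 3 by 118 and 117, while siMBD2 replicates 1 and 2 differed by 3.38. Control replicates 1 and 2 differed by 29.1, close to the 30.8 between siMBD2 replicates 1 and 3. From control replicate 3 they differed by 133 and 87.9.

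Mbd2 (chromosome 18, from 70568189 to 70626131, GRCm38.p6), the gene targeted by the siRNA, stood at 75.8, 83.2 and 72.5 CPM in the scramble libraries and at 35.7, 34.7 and 30.6 CPM in the siMBD2 libraries. It fell from 77.2 ± 5.47 to 33.7 ± 2.71 CPM (mean ± SD, n = 3 each), a fold of 0.436 (log2 fold change -1.20, SE 0.0867, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.000197). The control libraries held 72.9, 75.9 and 76.5 CPM and the KCC-07 libraries 75.1, 72.8 and 77.1 CPM, so that Mbd2 mRNA differed by a fold of 0.998 with the compound (edgeR adjusted p = 0.991). Mbd3, a related NuRD subunit, had log2 fold changes of -0.26 with KCC-07 (adjusted p = 0.373) and -0.06 with siMbd2 (adjusted p = 1), neither past the threshold. Adgrb1, which encodes the adhesion receptor BAI1, was close to the detection floor at 0.797 ± 0.519 CPM in control and 0.744 ± 0.499 CPM with KCC-07 (edgeR adjusted p = 0.933), and 0.740 ± 0.159 CPM with scramble against 0.911 ± 0.290 CPM with siMbd2 (edgeR adjusted p = 1).

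**Figure D1:**
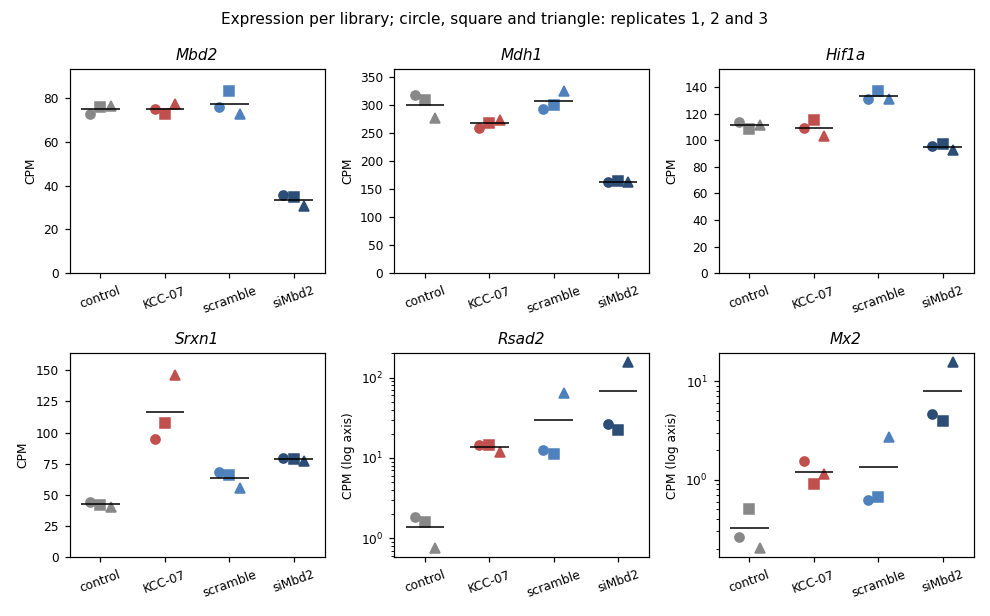
CPM (vertical axis) of Mbd2, Mdh1, Hif1a, Srxn1, Rsad2 and Mx2 in each library of the 4 groups (horizontal axis); the Rsad2 and Mx2 panels have log axes. Circles, squares and triangles are replicates 1, 2 and 3 and lines are group means (n = 3); Mbd2 lies between 30.6 and 35.7 CPM in the siMBD2 libraries and at 72.5 CPM or above in the others.

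Of the genes that rose with KCC-07 and met the naming rule, Tslp, an epithelial cytokine gene, had the largest log2 fold change. Tslp (chromosome 18, from 32815383 to 32819797), rose from 3.08 ± 2.09 to 33.4 ± 18.3 CPM (n = 3 each; log2 fold change 3.45, SE 0.559, edgeR adjusted p = 0.00839). The glutathione transferase gene Gstm2 (3.07), the glycosyltransferase gene Gcnt2 (3.01), the tight junction gene Cldn4 (2.92), the cytokine gene Il6 (2.87), the keratin gene Krt16 (2.78), the MHC class II invariant chain gene Cd74 (2.75), the autophagy gene Atg9b (2.65), the interleukin 18 receptor gene Il18rap (2.61) and Mal (2.58) rose by these log2 fold changes. Postn, which encodes the matrix protein periostin (chromosome 3, from 54361109 to 54391037), fell from 48.2 ± 27.8 to 5.79 ± 2.36 CPM (log2 fold change -3.06, SE 0.473, edgeR adjusted p = 0.00665). The chemokine gene Cxcl12 (chromosome 6, from 117168535 to 117181367) fell from 34.5 ± 8.80 to 5.11 ± 1.46 CPM (-2.76, SE 0.305, edgeR adjusted p = 0.00127). Cytl1 (-2.71), Scrg1 (-2.40), the protease inhibitor gene A2m (-2.28), Capn6 (-2.26), Olfml3 (-1.84), Plac9a (-1.83), Pou2af1 (-1.78) and Wscd2 (-1.68) fell by these log2 fold changes. Of these 20 genes, 14 stayed past the threshold whichever library was left out. The others did not: Cldn4, Plac9a and Wscd2 without control replicate 1 or 2, Il18rap without control replicate 1, Il6 without control replicate 2 or KCC-07 replicate 1 or 2, and Mal without control replicate 1 or 2 or KCC-07 replicate 3, with highest edgeR adjusted p of 0.0673, 0.0579, 0.0651, 0.0696, 0.0869 and 0.111. Without the libraries of batch 3, 19 of the 20 stayed past it, and Mal did not (edgeR adjusted p = 0.0571). Those fits all kept the siRNA libraries in the pooled spread. With the 6 libraries of the comparison fitted alone 0 of the 20 passed, and with the block as well 16 did. Tslp, Atg9b and Gcnt2 overlap genes on the opposite strand (4930455D15Rik, Nos3, and 5530402G07Rik among others), and Krt16 and Plac9a have near-identical copies, so those values are uncertain.

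In all, 844 genes changed with KCC-07 (534 rose and 310 fell, 255 of them at least 2-fold, 187 higher and 68 lower) at an edgeR quasi-likelihood Benjamini-Hochberg adjusted p under 0.05. The count rested on the spread pooled over the 4 groups: a fit of the 6 libraries alone called 1 gene, and with the replicate block 394, of which 276 were among the 844. It was 3251 with the replicate block over all libraries, 1874 with DESeq2, 2652 without the libraries of batch 3, and 403, 391 and 2134 without control replicates 1, 2 and 3. Several list members named below passed in neither fit of the 6 libraries alone, with or without the block. They were Marveld2, Uvrag, Rpl10a, Rpl14, Ndufb10, E2f1, Anln, Nek2, Cdk2ap1 and Lif.

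Genes of the antioxidant response rose with KCC-07. Of 27 measured targets of NRF2, the transcription factor of that response, 15 rose (20 rose and 1 fell adjusted over the list alone, 18 and 1 with the block), with a median log2 change of 0.73 and replicate-pair medians of 0.45, 0.58 and 0.72 (camera adjusted p = 3.62e-10; adjusted p = 0.215 with an estimated correlation). Srxn1, which encodes sulfiredoxin, rose from 42.3 ± 1.86 to 116 ± 26.7 CPM (n = 3 each; log2 fold change 1.46, SE 0.142, edgeR adjusted p = 0.000687). Gsr, the glutathione reductase gene, rose by 0.75, Gclc, a subunit of the enzyme that starts glutathione synthesis, by 0.73, and Osgin1 by 1.51. Of 28 epithelial junction and keratin genes 11 rose (17 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 1.35e-07; adjusted p = 0.254 with an estimated correlation). Ocln, the occludin gene, rose by 1.57 (3.45 ± 0.222 to 10.2 ± 2.28 CPM, edgeR adjusted p = 0.00626) and Marveld2, the tricellulin gene, by 0.96 (edgeR adjusted p = 0.0120). Of 31 targets of ATF4, the transcription factor of the integrated stress response, 5 rose (10 adjusted over the list alone) and all 31 lay above 0, with a median of 0.59 (camera adjusted p = 1.35e-07; adjusted p = 0.370 with an estimated correlation). Their replicate-pair medians were 0.36, 0.12 and 1.19, so that pair 3 stood highest, and the block called 14. Ddit4, an inhibitor of mTOR signalling, rose from 245 ± 22.8 to 472 ± 16.9 CPM (edgeR adjusted p = 0.00393). Slc7a11, the cystine transporter gene that is also an NRF2 list member, rose from 9.41 ± 6.07 to 48.4 ± 4.88 CPM (edgeR adjusted p = 0.00981). Of 29 p53 targets 5 rose (10 rose and 1 fell adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.000735; adjusted p = 0.254 with an estimated correlation). Mdm2, the p53 inhibitor gene, rose by 0.63 (67.0 ± 6.54 to 104 ± 13.6 CPM, edgeR adjusted p = 0.009). The block called 14 of them higher and 3 lower. Marveld2 and Slc7a11 overlap Gm24261 and Gm37854 on the opposite strand and are uncertain.

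Interferon and early response genes stood higher with KCC-07 as lists. None of 37 type I interferon response genes passed the edgeR threshold, over all genes or adjusted over the list alone, while 9 had an unadjusted p under 0.05 and DESeq2 called 3, and 24 rose and 1 fell with the replicate block. The list median was 0.77 (camera adjusted p = 0.00286; adjusted p = 0.699 with an estimated correlation), with replicate-pair medians of 0.80, 0.67 and 0.97. This list call ended without control replicate 3 (median 0.84, camera adjusted p = 0.0511) and without the libraries of batch 3 (median 0.65, camera adjusted p = 0.113). Rsad2, the antiviral protein viperin, stood at 1.39 ± 0.561 CPM in control and 13.8 ± 1.53 CPM with KCC-07 (log2 fold change 3.31, edgeR adjusted p = 0.0537, and 0.000221 with the block). Of 24 immediate early genes none passed over all genes, 7 rose adjusted over the list alone, 7 had an unadjusted p under 0.05, DESeq2 called 6 and the block 15 (median 0.48; camera adjusted p = 0.00539; adjusted p = 0.215 with an estimated correlation). Nr4a1, a nuclear receptor gene, stood at 30.2 ± 2.27 and 54.5 ± 4.20 CPM (edgeR adjusted p = 0.0559, and 0.00104 with the block). Dusp6, a phosphatase gene of ERK signalling, stood at 148 ± 68.4 and 363 ± 223 CPM (edgeR adjusted p = 0.0642, and 0.00068 with the block). The block also brought 4 further lists past the camera threshold, all higher: NF-kB and inflammatory cytokines (adjusted p = 8.54e-05), cholesterol synthesis (0.0283), aryl hydrocarbon receptor targets (0.0283) and mitochondrially encoded genes (0.0410). With the block and an estimated correlation their adjusted p were 0.121, 0.385, 0.385 and 0.455.

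Lysosome, endoplasmic reticulum and protease lists also stood higher with KCC-07. Of 26 lysosome and autophagy genes 3 rose (3 adjusted over the list alone; median 0.27, camera adjusted p = 0.00204; adjusted p = 0.430 with an estimated correlation), among them Uvrag, by 0.47 (edgeR adjusted p = 0.0134), which overlaps Gm45188 on the opposite strand and is uncertain. Of 23 unfolded protein response and chaperone genes 2 rose (4 adjusted over the list alone; median 0.13, camera adjusted p = 0.0320; adjusted p = 0.699 with an estimated correlation), among them the oxidase gene Ero1lb, by 0.91 (edgeR adjusted p = 0.0123). Of 23 matrix proteolysis and invasion genes 3 rose and 1 fell (7 and 3 adjusted over the list alone; median 0.44, camera adjusted p = 0.0320; adjusted p = 0.370 with an estimated correlation). The collagenase gene Mmp13 rose from 0.764 ± 0.272 to 4.15 ± 1.00 CPM (edgeR adjusted p = 0.0118). S100a4, a calcium-binding protein linked to metastasis, fell from 28.9 ± 2.31 to 15.5 ± 3.53 CPM (edgeR adjusted p = 0.0108), though it has a near-identical copy and is uncertain. These 3 list calls ended without KCC-07 replicate 3 (lysosome, camera adjusted p = 0.0555, and proteolysis, 0.192), without control replicate 3 (proteolysis, 0.161, and unfolded protein response, 0.948, its median there turning to -0.03) or without KCC-07 replicate 1 or 2 (unfolded protein response, 0.183 and 0.277). They also ended without the libraries of batch 3 (lysosome 0.164, unfolded protein response 0.0773, proteolysis 0.473), and the proteolysis call ended with the stricter filter on low counts (median 0.38, camera adjusted p = 0.0847). The proteolysis median was 0.44 without control replicate 3, 0.20 without KCC-07 replicate 3 and 0.15 without batch 3. The lysosome median was 0.16 without KCC-07 replicate 3 and 0.11 without batch 3.

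Ribosomal and respiratory chain genes shifted down together with KCC-07, by less than 1.5-fold. All 37 cytosolic ribosomal protein genes lay below 0, with a median log2 change of -0.32 (camera adjusted p = 2.26e-10; adjusted p = 0.430 with an estimated correlation), and 2 fell over all genes, 26 adjusted over the list alone and 25 with the block. Rpl10a fell from 457 ± 60.0 to 345 ± 16.4 CPM (edgeR adjusted p = 0.0368) and Rpl14 from 511 ± 77.1 to 389 ± 23.5 CPM (edgeR adjusted p = 0.04995). Both have near-identical pseudogenes, and Rpl10a also overlaps CT025652.2 on the opposite strand, so both are uncertain. Of 36 nuclear genes of oxidative phosphorylation 34 lay below 0 (median -0.22, camera adjusted p = 1.35e-07; adjusted p = 0.430 with an estimated correlation), and 1 fell over all genes, 13 adjusted over the list alone and 10 with the block. That gene was Ndufb10, a complex I subunit, at 68.3 ± 7.14 CPM in control and 53.9 ± 2.23 CPM with KCC-07 (edgeR adjusted p = 0.0465). Without any 1 of control replicates 1 and 2 and KCC-07 replicates 1, 2 and 3, none of these 3 genes stayed past the threshold (edgeR adjusted p up to 0.105, 0.145 and 0.121). They also did not pass with the 6 libraries of the comparison fitted alone, with or without the block. Replicate-pair medians were -0.47, -0.31 and -0.12 for the ribosomal and -0.46, -0.20 and -0.04 for the respiratory list, so that pair 3 stood nearest to 0. Removing a trend on length, GC content and mean expression from the blocked fit took the medians from -0.30 to -0.10 and from -0.22 to -0.04. Both lists were also lower in scramble against control, which shares the control libraries.

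Cell cycle, MYC target and NuRD lists stood lower with KCC-07, though the G1/S members that passed over all genes were higher. Of 40 G1/S and DNA replication genes 30 lay below 0 (median -0.18, camera adjusted p = 0.0181; adjusted p = 0.699 with an estimated correlation), yet 2 rose (2 adjusted over the list alone). E2f2 rose from 13.7 ± 1.46 to 22.4 ± 1.78 CPM (edgeR adjusted p = 0.0115) and E2f1 from 103 ± 16.1 to 147 ± 5.89 CPM (edgeR adjusted p = 0.0215), both transcription factors of S-phase entry. With the block 8 of the 40 fell. Of 35 G2/M genes (median -0.13, camera adjusted p = 0.0135; adjusted p = 0.699 with an estimated correlation) the cyclin gene Ccna2 fell, and Anln, an actin-binding protein of the cleavage furrow, and Nek2, a centrosome kinase gene, rose by 0.43 and 0.46. In that list 2 rose and 5 fell adjusted over the list alone, and 9 fell with the block. None of 29 MYC target and ribosome biogenesis genes passed over all genes or over the list alone, 5 had an unadjusted p under 0.05, DESeq2 called 2 and the block 4, all lower (median -0.17, camera adjusted p = 0.00823; adjusted p = 0.699 with an estimated correlation). Of 14 MBD2-NuRD subunit genes 1 fell, Cdk2ap1 (2 adjusted over the list alone, 4 with the block; median -0.17, camera adjusted p = 0.0320; adjusted p = 0.370 with an estimated correlation). Without KCC-07 replicate 3 all 4 list calls ended (G1/S 0.725, G2/M 0.0793, MYC 0.520, NuRD 0.0518), and the G1/S call also ended without control replicate 1 (0.113) and the NuRD call without control replicate 3 (0.172) or KCC-07 replicate 1 (0.0538). Without the libraries of batch 3 the G1/S (0.0932), MYC (0.522) and NuRD (0.164) calls ended too. Nek2 overlaps Gm38037 on the opposite strand and is uncertain. E2f1 and Nek2 did not pass without control replicate 1 (edgeR adjusted p = 0.0638 and 0.0796), nor Cdk2ap1, which has a near-identical copy and is uncertain, without control replicate 1 or 2 or KCC-07 replicate 1 or 3 (up to 0.0937). With the 6 libraries of the comparison fitted alone, with or without the block, E2f1, Anln, Nek2 and Cdk2ap1 did not pass.

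Of the 34 lists tested, 15 passed the camera threshold in KCC-07 against control, 9 higher and 6 lower, and none did with an estimated correlation, with or without the block, in this comparison or in the siMbd2 comparison. Without the libraries of batch 3 the number was 10, of which 8 were among the 15. By fry, which asks whether the genes of a list move on balance one way, 13 lists passed, 7 of them among the 15. Median, mean and test had the same sign in every list that passed. They differed for the heat shock list (median -0.03, mean 0.10, camera lower, fry higher, camera adjusted p = 0.966). In siMbd2 against scramble they differed for the ATF4 (median 0.03, mean 0.03, camera lower), luminal (0.05, -0.09, lower), fatty acid (-0.04, 0.01, lower) and epithelial (0.01, -0.01, lower) lists, none of which passed. In scramble against control they differed for 6 lists, none of which passed, the NF-kB list (-0.97, -0.79, higher) among them. Among markers of other cell types, 3 of 15 leukocyte markers and 5 of 12 fibroblast markers were measured. All 3 leukocyte markers lay above 0 (median 2.04) and 1 rose, Cd74 (2 adjusted over the list alone and with the block). The highest levels in a control and a KCC-07 library were 0.972 and 7.55 CPM for Cd68, 4.46 and 7.72 CPM for Csf1r, and 0 and 0.116 CPM for Ptprc, the pan-leukocyte gene. Csf1r overlaps Hmgxb3 on the opposite strand and is uncertain. Of the fibroblast markers Gsn rose and Postn fell (median -0.52, camera adjusted p = 0.0642), with replicate-pair medians of -0.15, -0.51 and -1.11.

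**Figure D2:**
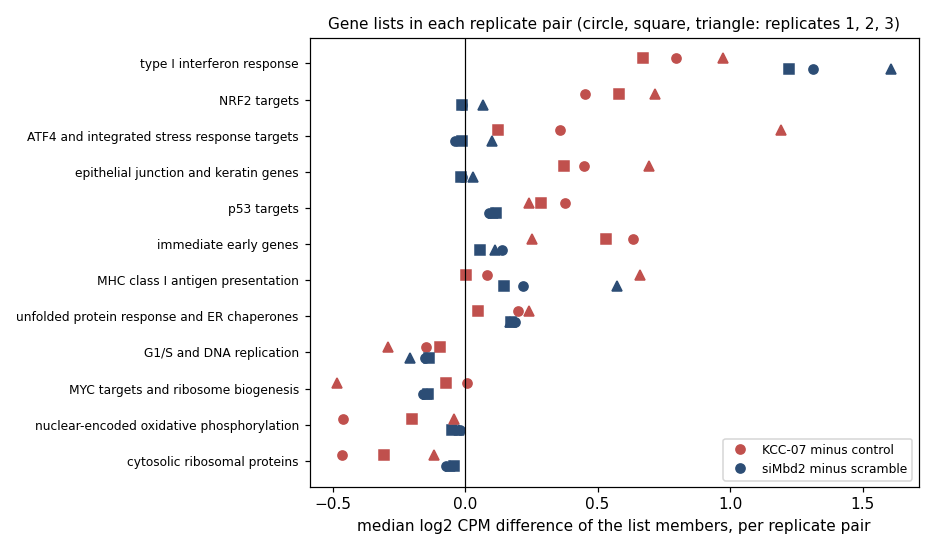
Median log2 CPM difference (horizontal axis) of 12 fixed gene lists (vertical axis) for each replicate pair, KCC-07 minus control in red and siMbd2 minus scramble in blue. The interferon list lies between 0.67 and 0.97 with KCC-07 and between 1.22 and 1.61 with siMbd2, and the ribosomal protein list between -0.47 and -0.12 with KCC-07.

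Knockdown of Mbd2 lowered 6 genes, Mbd2 itself among them, and no gene rose past the threshold. Mdh1, the cytosolic malate dehydrogenase gene, fell from 307 ± 16.6 to 163 ± 1.23 CPM (n = 3 each; log2 fold change -0.91, SE 0.0776, edgeR adjusted p = 0.000577). Rcn2, an endoplasmic reticulum calcium-binding protein gene (chromosome 9, from 56041845 to 56061882), fell from 88.4 ± 1.19 to 54.1 ± 3.28 CPM (edgeR adjusted p = 0.00423). Twf1, an actin monomer-binding protein gene, fell from 110 ± 1.23 to 74.3 ± 1.76 CPM (edgeR adjusted p = 0.0206). Selenot, a selenoprotein gene, fell from 201 ± 4.19 to 136 ± 11.95 CPM, and Hif1a, the hypoxia-inducible factor gene (chromosome 12, from 73901375 to 73947530), from 133 ± 3.56 to 95.2 ± 2.14 CPM (edgeR adjusted p = 0.0496 for each). In the control cells, Hif1a stood at 111 ± 2.60 CPM, lower than with scramble (edgeR adjusted p = 0.0434). Twf1 and Hif1a overlap genes on the opposite strand, Irak4 and Gm15283, and are uncertain. The identifier of Mdh1 was not found with its version in the annotation, so Mdh1 was not checked for overlaps or copies. Mbd2 and Mdh1 passed whichever library was left out. Rcn2 did not pass without siMBD2 or scramble replicate 2 (edgeR adjusted p up to 0.0547), and Twf1, Selenot and Hif1a did not pass without any 1 of the 6 libraries (up to 0.272, 0.347 and 0.347). With DESeq2 size factors 2 of the 6 gene calls ended, and without a filter on low counts 3 did.

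Of the 14935 genes 786 had an unadjusted p under 0.05 in this comparison, and 1582 with the replicate block, against 747 for no effect. The count of 6 by the edgeR quasi-likelihood test rested on the pooled spread. It was 112 (63 higher and 49 lower) with the replicate block, 171 with the 6 libraries alone and 2753 with those libraries and the block. DESeq2 gave 85 (24 higher and 61 lower), and the fit without the libraries of batch 3 gave 12, 2 of them among the 6. Leaving out scramble replicate 2 or siMBD2 replicate 2 left 2 genes, and leaving out any other siRNA library 3.

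Interferon genes stood higher with siMbd2 than with scramble in each replicate pair. All 37 type I interferon response genes lay above 0, with a median log2 change of 1.42 and replicate-pair medians of 1.31, 1.22 and 1.61 (camera adjusted p = 6.07e-21; adjusted p = 0.635 with an estimated correlation). None passed the edgeR threshold over all genes or adjusted over the list alone, 22 had an unadjusted p under 0.05 and DESeq2 called 2. With the block 25 rose over all genes and 36 adjusted over the list alone, and camera with the block and an estimated correlation gave adjusted p = 0.0738. Mx2, of an antiviral GTPase gene family, stood at 1.35 ± 1.20 CPM with scramble and 8.03 ± 6.47 CPM with siMbd2 (log2 fold change 2.58, edgeR adjusted p = 0.347, and 0.00837 with the block). The GENCODE annotation types Mx2 as a polymorphic pseudogene. Ddx58, the RNA sensor RIG-I, stood at 183 ± 57.9 and 371 ± 177 CPM (edgeR adjusted p = 0.459, and 0.0029 with the block). The libraries of replicate 3 stood highest in both groups. Mx2 was at 0.628, 0.673 and 2.73 CPM in scramble replicates 1, 2 and 3 and at 4.65, 3.97 and 15.5 CPM in siMBD2 replicates 1, 2 and 3. All 18 MHC class I antigen presentation genes lay above 0, with a median of 0.36 (camera adjusted p = 5.70e-07; adjusted p = 0.635 with an estimated correlation), and none passed over all genes or the list alone, with 3 at an unadjusted p under 0.05 and 0 by DESeq2. Tap1, a peptide transporter gene, stood at 19.2 ± 5.75 and 48.3 ± 35.1 CPM, uncertain for its overlap with Psmb9 on the opposite strand, and the MHC list call ended without siMBD2 replicate 3 (camera adjusted p = 0.0563). Of 23 unfolded protein response genes none passed over all genes or the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 (median 0.17, camera adjusted p = 0.00352; adjusted p = 0.740 with an estimated correlation). Pdia4 of this list passed with the 6 siRNA libraries fitted alone, with and without the block.

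Proliferation genes stood slightly lower with siMbd2. Of 40 G1/S and DNA replication genes 38 lay below 0, with a median of -0.16 (camera adjusted p = 7.13e-08; adjusted p = 0.635 with an estimated correlation). None passed over all genes, 1 fell adjusted over the list alone, 5 had an unadjusted p under 0.05 and DESeq2 called 2. Rrm2, a ribonucleotide reductase subunit gene, stood at 292 ± 12.6 and 226 ± 8.17 CPM (edgeR adjusted p = 0.197), and Mcm3, a subunit of the replicative helicase, at 298 ± 22.4 and 180 ± 16.9 CPM (edgeR adjusted p = 0.423). Rrm2 and Mcm3 both passed with the 6 siRNA libraries fitted alone, with and without the block, so their main result rests on the pooled spread. All 29 MYC target genes lay below 0 (median -0.15, camera adjusted p = 5.01e-05; adjusted p = 0.704 with an estimated correlation). The medians were -0.07 over 35 G2/M genes (camera adjusted p = 0.000342; adjusted p = 0.666 with an estimated correlation), -0.13 over 29 glycolysis and hypoxia genes, 2 of which carry the symbol Aldoa (camera adjusted p = 0.00372; adjusted p = 0.635 with an estimated correlation) and -0.10 over 24 homologous recombination genes (camera adjusted p = 0.0118; adjusted p = 0.635 with an estimated correlation). Over all genes none of these members passed, and adjusted over the list alone 3 G2/M genes fell and no member of the other 3 lists passed. At an unadjusted p under 0.05 stood 3 G2/M, 2 glycolysis, 0 homologous recombination and 0 MYC target genes, and DESeq2 called 2, 0, 0 and 0 of them. With the 6 siRNA libraries fitted alone and the block, Aurkb of the G2/M list and Egln1 of the glycolysis and hypoxia list passed. Of 14 MBD2-NuRD genes 1 fell, Mbd2 itself (1 adjusted over the list alone; median -0.06, camera adjusted p = 0.0324; adjusted p = 0.635 with an estimated correlation). That call rests on the siRNA's own target: without Mbd2, a test chosen after the result was seen, the other 13 genes did not pass (camera adjusted p = 0.320), and 8 lists did.

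The 9 list calls in this comparison (3 higher and 6 lower) numbered 6 without the libraries of batch 3, all 6 among the 9, and none by fry. The calls that ended without batch 3 were NuRD (median -0.09, camera adjusted p = 0.0742), glycolysis (median -0.14, 0.0742) and homologous recombination (median -0.08, 0.128). The G2/M and homologous recombination calls ended without siMBD2 replicate 3 (camera adjusted p = 0.251 for each), the glycolysis call without scramble replicate 3 (0.0730), and the NuRD call without siMBD2 replicate 2 (0.0643), without scramble replicate 3 (0.0628) and with the replicate block (0.0849). The block brought the NF-kB (0.0322) and mitochondrially encoded (0.00987) lists past the threshold, both lower (adjusted p = 0.413 for each with the block and an estimated correlation).

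No gene passed the edgeR threshold in both comparisons, among 844 with KCC-07 and 6 with siMbd2, where independent lists would share 0.214 genes higher with the compound and lower with the knockdown and 0.124 lower in both. Of the NRF2 list, 4 genes responded more to KCC-07 than to siMbd2 (17 more and 1 less adjusted over the list alone; camera adjusted p = 2.38e-08; adjusted p = 0.441 with an estimated correlation). They were Gsr, Srxn1, Me1, the malic enzyme gene, which overlaps A330041J22Rik on the opposite strand and is uncertain, and Gclc, with differences of 0.70, 1.15, 0.73 and 0.75 on the log2 scale (edgeR adjusted p of 0.0312, 0.0312, 0.0347 and 0.0358). None of the 4 passed without control replicate 1, KCC-07 replicate 2, scramble replicate 1 or 2 or any siMBD2 replicate, and 2 or more of them did not pass without control replicate 2, KCC-07 replicate 1 or scramble replicate 3 (edgeR adjusted p up to 0.127). With siMbd2 the median of the NRF2 list was 0.00 (camera adjusted p = 0.453). The effects were measured from different control groups, and NRF2 targets differed between those groups, as given below. A difference in baseline or between the experiments was therefore not separated from the compound. Mbd2 differed by 1.19 between the effects (edgeR adjusted p = 0.00539). With the replicate block 40 genes changed the same way in both, 34 higher and 6 lower. Independent lists would share 8.04 and 4.41 (two-sided Fisher exact test over genes, which are not independent, adjusted over 4 pairs of directions: p = 2.19e-14 and 0.447). In opposite directions, 10 genes were higher with KCC-07 and lower with siMbd2, and 2 the reverse. Independent lists would share 6.26 and 5.67 (adjusted p = 0.172 for each by the same Fisher test). Of the 34, 19 belonged to the 37 interferon response genes. DESeq2 gave 8 shared genes, and the edgeR test gave 1 without the libraries of batch 3, 4 without control replicate 3 and 3 without KCC-07 replicate 3. Across all genes, the log2 fold changes of the 2 comparisons, which share no library, correlated with r = 0.05 and rho = 0.03 (exact permutation of the library labels within the arms, 400 assignments, two-sided p = 0.430 for r, of which 0.01 is the smallest possible). In all, 98 genes responded differently to the compound and to the knockdown (72 more positive and 26 more negative with KCC-07) by the edgeR quasi-likelihood test of the difference. That count was 1030 with the replicate block, 617 with DESeq2, 176 without a filter on low counts and 1589 without the libraries of batch 3. Leaving out any 1 library moved it by over 1.5 times, from 11 without siMBD2 replicate 2 to 351 without control replicate 3.

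Scramble-transfected cells differed from control cells at 1313 genes (704 rose and 609 fell; at least 2-fold, 93 rose and 191 fell), the background between the control groups of the 2 arms, in which transfection and any difference between the experiments cannot be separated. Lipid synthesis lists stood higher. Of 24 cholesterol synthesis genes 11 rose (13 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 1.42e-08; adjusted p = 0.499 with an estimated correlation). Of 16 fatty acid synthesis genes 7 rose (10 rose and 1 fell adjusted over the list alone), with a median of 0.37 (camera adjusted p = 4.28e-07; adjusted p = 0.0552 with an estimated correlation). The desaturase gene Scd1 rose from 1369 ± 199 to 3598 ± 245 CPM (n = 3 each; edgeR adjusted p = 0.00128). Of 29 MYC target and ribosome biogenesis genes 10 rose (22 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 2.67e-09; adjusted p = 0.542 with an estimated correlation), among them Ppan by 0.95 and Rrp12 by 0.86. Of 27 NRF2 targets 10 rose and 1 fell (15 and 2 adjusted over the list alone; median 0.36, camera adjusted p = 0.000177; adjusted p = 0.499 with an estimated correlation). Gsr rose by 0.51 and the transaldolase gene Taldo1 fell by 0.72. Of 37 interferon response genes 5 rose (19 adjusted over the list alone, 13 with the block), with a median of 1.41 (camera adjusted p = 4.98e-06; adjusted p = 0.632 with an estimated correlation). Rsad2 rose from 1.39 ± 0.561 to 29.3 ± 30.3 CPM (edgeR adjusted p = 0.0166), at 12.6, 11.1 and 64.3 CPM in scramble replicates 1, 2 and 3. It lost its call without the libraries of batch 3 (0.0651) or without control replicate 1 or 2 (up to 0.0591). Of the other members that rose, Ifit1, Oasl1 and Oas1a did not pass without the libraries of batch 3 either (edgeR adjusted p = 0.175, 0.0788 and 0.173). Ifit1 and Oas1a did not pass without any 1 of the 6 libraries (up to 0.130 and 0.143), nor Oasl1 without control replicate 1 or 2 or scramble replicate 3 (up to 0.0722). Oasl1 overlaps Gm13822 on the opposite strand and Oas1a has a near-identical copy, so both are uncertain.

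Of 35 G2/M genes 5 fell between control and scramble (9 adjusted over the list alone; median -0.20, camera adjusted p = 0.00187; adjusted p = 0.632 with an estimated correlation). All 37 ribosomal protein genes lay below 0 (median -0.24, camera adjusted p = 8.68e-05; adjusted p = 0.650 with an estimated correlation), and none passed over all genes or the list alone, with 12 at an unadjusted p under 0.05 and 0 by DESeq2. Further lists passed camera without an estimated correlation. The epithelial (5 rose and 1 fell, over all genes and adjusted over the list alone, median 0.33, adjusted p = 0.000275, 0.499 with an estimated correlation), heat shock (0.25, 0.00122, 0.440), mitochondrially encoded (0.51, 0.00187, 0.632), lysosome (0.24, 0.00778, 0.632), MHC class I (0.25, 0.0322, 0.650) and G1/S (0.11, 0.0307, 0.650) lists were higher. The oxidative phosphorylation list was lower (-0.14, 0.0276, 0.650). Pdgfrb, a growth factor receptor gene and fibroblast marker, fell from 16.6 ± 0.652 to 3.29 ± 0.968 CPM (edgeR adjusted p = 0.00966), and the serine protease gene Tmprss4 from 11.6 ± 2.78 to 2.46 ± 0.424 CPM (edgeR adjusted p = 0.00325), though Tmprss4 overlaps BC049352 on the opposite strand and is uncertain. The edgeR count of 1313 was 2062 with a block that takes the replicate numbers of the arms as shared, which the labels leave unclear, 2299 with DESeq2, 332 with the 6 libraries alone and the block, and 1973 without the libraries of batch 3. It was 619, 579 and 3125 without control replicates 1, 2 and 3, and 316, 349 and 579 without scramble replicates 1, 2 and 3. This comparison shares the control libraries with the KCC-07 comparison and the scramble libraries with the siMbd2 comparison, so its lists were not tested against theirs.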

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

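Of the tests in this part, the fits without the libraries of batch 3 and the splits of both arms that part all replicate pairs were chosen after the result was seen. A test of the difference between the KCC-07 effect and the siMbd2 effect (the interaction term of the edgeR quasi-likelihood fit, Benjamini-Hochberg adjusted) picked out 98 genes, 72 more positive and 26 more negative with KCC-07. The 5 most positive differences, as the log2 fold change with KCC-07 minus that with siMbd2, were Tslp at 4.15 (edgeR adjusted p = 0.0412), Spn, the sialophorin gene, at 3.65 (0.0136), Gstm2 at 3.37 (0.0154), Gcnt2 at 2.77 (0.0476) and Tmprss2 at 2.64 (0.00796). Spn stood at 1.99 ± 0.358 CPM in control, 9.73 ± 4.58 CPM with KCC-07, 1.67 ± 0.227 CPM with scramble and 0.648 ± 0.226 CPM with siMbd2 (SD, n = 3 each). The 5 most negative were Cxcl12 at -3.16 (0.00959), A2m at -2.66 (0.00676), Scrg1 at -2.62 (0.0434), Cytl1 at -2.59 (0.00771) and Oxtr, the oxytocin receptor gene, at -2.34 (0.0347). Oxtr stood at 2.88 ± 1.05 CPM in control, 0.810 ± 0.234 CPM with KCC-07, 3.45 ± 0.279 CPM with scramble and 4.92 ± 0.711 CPM with siMbd2. Tmprss2, Cxcl12, A2m and Cytl1 stayed past the threshold whichever of the 12 libraries was left out, and all 10 did without the libraries of batch 3. Spn did not pass without siMBD2 replicate 2 (edgeR adjusted p = 0.0511), and Gstm2 without any siMBD2 replicate or scramble replicate 2 (up to 0.0624). Tslp did not pass without control replicate 1, KCC-07 replicate 2 or any siRNA library (up to 0.125). Gcnt2, Oxtr and Scrg1 did not pass without control replicate 1 or 2, KCC-07 replicate 1 or any siRNA library, and Gcnt2 and Oxtr also without KCC-07 replicate 2 (up to 0.142, 0.125 and 0.137). Tslp and Gcnt2 overlap genes on the opposite strand and are uncertain.

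Other splits of the libraries were tried for each count. Of 100 splits of the 12 libraries within the arms, drawn from 200, 1, the real one, gave as many genes as the 98 of the difference, and the highest of the others gave 82, a share under 0.05. That draw ignored the replicate pairs. Of the 32 splits that part all 3 pairs in both arms, 2 gave as many, the real one and the one that swaps the siMBD2 and scramble labels, which gave 140 and was not in the draw. That share is 0.0625, so chance assignment was not excluded once the pairs were kept. High counts came with the drug arm as labelled, and drawn splits that mixed the drug arm gave at most 2, so the 98 followed the KCC-07 labels more than the siRNA ones. For the comparisons of 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 844 genes for KCC-07 against control (highest other 2, and 0 among the 3 others that part all 3 replicate pairs), 6 for siMbd2 against scramble (highest other 0) and 1313 for scramble against control (highest other 0), and in each 1 of the 10 splits, the real one, reached that number. For lists, the real split gave 15 with KCC-07 (highest other 12, also among the others that part all 3 pairs), reached by 1 of the 10 splits. With siMbd2 it gave 9, which 4 of the 10 splits reached, the highest other giving 12. The 3 other splits that reached it kept both libraries of replicate 3 on the same side, the highest among the others that part all 3 pairs gave 7, and the replicate block gave 10 lists. The count of genes changed the same way by KCC-07 and siMbd2 was 0, which all 100 splits reach by construction, so the splits say nothing about it.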

How the results depend on the processing

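The fits without the libraries of batch 3, the fit of 6 libraries alone with the block, the block together with the omission of batch 3, and the block with an estimated correlation were chosen after the data were seen. Mbd2 fell by 1.13 to 1.24 on the log2 scale and passed in all 15 alternatives tried on it, and r between the effects stayed between 0.01 and 0.06. With the replicate block the counts for KCC-07, siMbd2, their difference, scramble against control (a block shared across arms) and genes changed the same way were 3251, 112, 1030, 2062 and 40. With DESeq2 they were 1874, 85, 617, 2299 and 8, and without the libraries of batch 3 they were 2652, 12, 1589, 1973 and 1, or with the block as well 3577, 73, 1325, 5888 and 31. The fit of 6 libraries alone gave 1 gene for KCC-07 and 171 for siMbd2, and with the block 394, 2753 and, for scramble against control, 332, with 64 changed the same way by both. Taken over all genes, the drug-arm replicates differed more than the siRNA-arm ones. Pooling the spread thus tends to lower it for the drug arm and to raise it for the siRNA arm. Single genes can go the other way, such as Rsad2, whose spread with scramble exceeded that in control and with KCC-07. Of the 394 genes 80.5% were higher, against 63.3% of the 844. Without a filter on low counts the difference had 176 genes. The threshold of 0.01 left 145, 3, 10 and 267 genes for KCC-07, siMbd2, the difference and scramble against control, and that of a 2-fold change 255, 1, 62 and 284, by construction. Leaving out 1 library gave 391 to 2134, 2 to 3, 11 to 351 and 316 to 3125 genes, and 0 to 4 changed the same way. The highest counts for KCC-07, the difference and scramble against control each came without control replicate 3. The causes of these shifts were not tested. Lists past the threshold numbered 11 to 19 with KCC-07 and 8 to 11 with siMbd2 when 1 library was left out. With an estimated correlation camera called 0 lists in either comparison, and 0 with the block as well, and fry called 0 with siMbd2. Of 204 leave-one-out checks of KCC-07 lists 13 lost a call, 15 gained one and 1 turned: the median of the unfolded protein response list, 0.13 with all libraries, was -0.0277 without control replicate 3 and 0.295 without KCC-07 replicate 3 (the cause was not tested). Of 444 such checks of named KCC-07 genes 67 lost a call and 9 gained one, of 138 of named siMbd2 genes 20 lost one, of 180 of the difference 79 and of 120 of scramble against control 33, with no change of sign. The block in the fit of all libraries ended no gene call named here and the NuRD list call with siMbd2, and brought 12 KCC-07 genes, 3 siMbd2 genes and the 6 lists given beside their results past the threshold; it changed no other call of a named gene or list. Adgrb1 rests on 5 to 45 counts per library, and whether depth limited its test was not examined.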

Other observations

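The tests of leukocytes, single replicate pairs, transfected RNA and the AU-rich element, and the use of the spread as a margin for the ribosomal list, were chosen after the results were seen.

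Further groups moved in part with KCC-07. Of 14 mammary luminal genes 3 rose (4 rose and 1 fell adjusted over the list alone; median 0.15, camera adjusted p = 0.0660), with Foxa1, a luminal transcription factor, at 11.97 ± 1.67 CPM in control and 32.3 ± 3.01 CPM with KCC-07 (SD, n = 3 each; log2 fold change 1.43, edgeR adjusted p = 0.000572). Of 18 Wnt and Notch targets 4 rose (5 rose and 1 fell adjusted over the list alone; median 0.41, camera adjusted p = 0.0642). Notch3 rose from 3.63 ± 1.51 to 15.9 ± 9.87 CPM (edgeR adjusted p = 0.0142), but did not pass without control replicate 1 or 2 (up to 0.0601). It overlaps Gm17276 on the opposite strand and is uncertain. Wif1, a secreted Wnt inhibitor and the member of the list of tumour suppressors often silenced by methylation that passed, fell from 31.0 ± 5.43 to 13.4 ± 3.21 CPM (edgeR adjusted p = 0.00843). That list of 20 measured genes had 1 fall (2 rose and 2 fell adjusted over the list alone; median 0.13, camera adjusted p = 0.867).

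Of 25 NF-kB and inflammatory cytokine genes 3 rose with KCC-07 (3 adjusted over the list alone; median 0.48, camera adjusted p = 0.0541, and 8.54e-05 with the replicate block, or 0.699 and 0.121 with an estimated correlation), among them Lif, a cytokine gene, from 260 ± 57.7 to 455 ± 35.1 CPM (edgeR adjusted p = 0.0144). Of 30 germline genes that DNA methylation keeps silent in somatic cells 5 were measured and 1 rose (3 adjusted over the list alone; median 1.41, camera adjusted p = 0.0580): Tex19.1, from 0.121 ± 0.0236 to 1.13 ± 0.374 CPM (edgeR adjusted p = 0.00700). Rhox5 stood at 0.607 ± 0.392 CPM in control and 1.85 ± 0.479 CPM with KCC-07 (edgeR adjusted p = 0.0507). Tex19.1 and Rhox5 were both close to the detection floor in control. The filter on low counts ran over all 4 groups, so a member could be kept through its KCC-07 libraries alone. That can tilt the median of the measured members upward. With siMbd2 none of the 5 germline genes passed over all genes or the list alone, 0 had an unadjusted p under 0.05 and DESeq2 called 0 (median -0.48, camera adjusted p = 0.497). The list differed between the effects by a median of 1.99 (camera adjusted p = 0.0326; adjusted p = 0.458 with an estimated correlation). The same filter can tilt this difference upward. With siMbd2 the replicate-pair medians of the list were 0.06, -0.93 and 0.06.

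The higher interferon genes after siMbd2 were weighed against technical sources. Leukocytes in the culture are argued against by Ptprc, at 0 CPM in each siMBD2 library, and a single replicate pair by the smallest of the pair medians, 1.22. Transfected RNA stays open: the list stood 1.41 higher with scramble than in control cells, but transfection cannot be told apart from other differences between the experiments. The prediction for this source also had the list not higher with KCC-07, which brings no RNA, but there its median was 0.77. The values of 1.41 and 0.77 share the control libraries, so they are not independent, and what those libraries contribute was not tested. The siMBD2 and scramble cells both received RNA, so it may differ in amount or in sequence between them, which was not measured. An effect of lower Mbd2 also stays open.

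The lower ribosomal and oxidative phosphorylation genes with KCC-07 were weighed against library scaling and against transcript length and GC content. A scaling factor moves all genes alike, so exchanging it for DESeq2 size factors is no test. The lists lay at -0.32 and -0.23 relative to all genes (with the block), a gap that a scaling factor cannot make. After a trend on length, GC content and mean expression was removed, the oxidative phosphorylation median went from -0.22 to -0.04. That is percentile 17.6 of 10000 matched random lists, inside their middle 95%. The trend was fitted to the KCC-07 changes of genes outside these lists and included mean expression. It can thus also remove an effect of the compound, so the test cannot tell whether the trend or the compound lowered this list. The ribosomal median went from -0.30 to -0.10 (SE 0.0210), at percentile 2, against a lower bound of -0.10 for the middle 95% of matched lists. The margin was smaller than the SE, so the trend and an effect on this list may not be separated here. Both lists also stood lower in scramble against control, which shares the control libraries. What the control libraries contribute to the lower values with KCC-07 was not tested.

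A hypothesis was tested for the genes that fell with siMbd2: that part of them carry matches to the seed of the transfected siRNA, whose sequence is not given in the sources used here. Of all 16384 words of 7 bases in 3' UTRs, GCCTAGT had the lowest t, -7.25 (777 genes, mean shift -0.07 on the log2 scale; highest t of any word 5.86), with -5.85, -6.36 and -5.96 in the 3 replicate pairs and -0.80 with KCC-07. Because the word was picked as the lowest over these same pairs, its low t in each pair follows in part from that choice. The word occurs in the Mbd2 mRNA, as do 7 of the 8 lowest words against 2 of the 8 highest and 12.6% of all words. Those lowest words overlap one another, as GCCTAGT and CCTAGTA do, so they are not independent matches. GCCTAGT lies in the 3' UTRs of Hif1a, Mdh1 and Twf1, while GACATTG (t -6.10), also in the Mbd2 mRNA, lies in those of Rcn2 and Selenot. The prediction written before concerned the single lowest word. GCCTAGT was in 3 of the 5 genes called besides Mbd2, against 6.20% of other genes. All 5 had one of the words GCCTAGT and GACATTG, against 15.2% of other genes. GACATTG was taken from the same scan after its values were seen, so this share follows in part from that choice. The result is consistent with seed-mediated effects of siRNAs against Mbd2 on these genes and leaves open how many of the changes follow from lower Mbd2.

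For KCC-07, a hypothesis was that mRNAs with an AU-rich element, which marks short-lived mRNAs, are higher. It was formed from TATTTAT, which had the highest t of all 16384 words in these data. In the 3' UTR it had t = 13.4 (mean shift 0.11 on the log2 scale; 12.7, 10.5 and 11.6 in the replicate pairs), against a median of 2.44 for the 21 words of the same base composition, and t = 0.49 with siMbd2. In scramble against control, which shares the control libraries, it had t = 5.77, and what the control libraries contribute to each value was not tested. Because the word was picked as the highest, its distance from words of the same composition and its height in each pair follow in part from that choice, and the hypothesis stays open. The difference between the comparisons was not tested, and mRNA stability was not measured.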
